A study of Mus musculus with 47 samples.

How the data were processed

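RNA from about 1500 to 10000 mouse cells per library was amplified with a SMART-Seq HT kit and made into libraries with a Nextera XT kit, per the labels' protocols. The deposited values are expected counts per gene, 1 file per library, as RSEM writes them per the file headers. The submitters' processing notes list STAR 2.7.7a, Picard 2.25.0 and RSEM 1.3.3 and the builds mm10 and GRCm38, without a role or order for any of them. Whether duplicate reads were removed, and which annotation was used, is not given in the sources used here. Neither kit marks the strand of the RNA, so overlapping and antisense genes cannot be separated, and neither adds molecular identifiers. Each file held 21000 genes, with 22 to 66 values that were not whole, and the expected counts were rounded to whole numbers before any test. Library totals ran from 14660655 to 43084068 (median 28884353).

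Groups and replicate numbers were taken from the titles of the 47 libraries, which gave 17 groups. For replicates 1 and 2 of untransduced cultured cDC1 and of cultured pre-cDC2, title and file name exchange the cell types. These 4 libraries were left out of the main tests and their groups stand on replicate 3 alone, so each such arm borrows its spread from the other groups. Primary CDP and primary splenic cDC1 have 1 library each and were not tested. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom was 18.4, between replicates 1 and 2 of primary bone marrow pre-cDC1.

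Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood F test with TMM normalisation and its default filter on low counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. Libraries were fitted by family, so that related groups share an estimate of the spread: 12 pre-cDC1 libraries of 4 genotypes, 9 transduced cDC1 libraries, 17 cultured libraries of all stages, 11 primary libraries, and 12 MDP and pre-cDC1 libraries from culture and bone marrow. The model held the group alone. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are scaled by TMM over all 47 libraries. Unless another tool is named, every adjusted p for a gene is from edgeR. Folds against a group with 0 counts use a floor of 3 counts over that group, and ratios against 1 to 3 counts carry a 95% counting interval. Comparisons that share control libraries were set beside 20 simulations of unchanged groups against the same controls.

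Gene lists were tested with camera, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The 21 lists cover cDC1, cDC2 and pDC identity, monocytes and macrophages, neutrophils and granules, stem cells and progenitors, B cells, T, NK and innate lymphoid cells, and erythroid cells, mast cells and basophils. They also cover MHC class II, class I with cross-presentation, interferon-stimulated genes, cell cycle, DC maturation, DC transcription factors, immediate early and stress genes, cholesterol synthesis, glycolysis and hypoxia, the genes around Irf8, sex-linked genes and mitochondrially encoded genes. The last list had 0 of 13 members among the genes used and was not analysed here, and of the sex-linked list 4 of 6 were used. A pair of further lists held up to 100 genes with the smallest adjusted p and a log2 fold change of at least 2 in either direction between primary bone marrow pre-cDC1 and MDP, and served only in the genotype and rescue comparisons.

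Genes were named by rule: Irf8; the 5 largest rises and falls among called genes whose replicates do not overlap between the groups and whose higher mean is at least 10 CPM, leaving out Gm, Rik and -ps symbols; and up to 4 members of each list with the smallest adjusted p, with other list members where a list needed them. Results that need a few of these genes are not reported here. By chance 10% of genes do not overlap in a comparison of 3 with 3. The groups, tests, lists, naming rule and other settings to try, except a pair named below, were fixed before the data were examined. The alternatives were DESeq2 in place of edgeR, DESeq2 size factors in edgeR, no filter on low counts, the replicate number as a block, only the groups compared in the fit, each library left out in turn, the conflicting libraries kept under their titles, and all libraries in 1 fit. A pair was added after seeing the data: single-transcript genes with a mean of at least 0.8 counts per base, called near the count limit, left out, and replicate 3 of the primary groups left out.

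Each fit was tested on simulated counts with 200 genes changed, 50 at each of 4 fold sizes. For d32 against WT, 14 of 50 genes changed 2-fold and 35 of 50 changed 4-fold were recovered among 11373 genes. In primary bone marrow, for pre-cDC1 against MDP, 0 of 50 changed 2-fold and 8 of 50 changed 4-fold were recovered among 12741 genes. Gene positions and transcript numbers are from the GRCm38.p6 annotation.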

Results

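RNA sequencing libraries were made from mouse dendritic cells (DCs) and their progenitors, 47 libraries in 17 groups. The monocyte-dendritic cell progenitor (MDP) and the common dendritic cell progenitor (CDP) lie upstream of the committed precursors pre-cDC1 and pre-cDC2, which give rise to the conventional DC subsets cDC1, specialised in cross-presenting antigen to CD8 T cells, and cDC2. Cells came from cultures with the cytokine Flt3 ligand or directly from bone marrow and spleen, the latter called primary cells. Most groups held 3 libraries, and primary CDP and primary splenic cDC1 held 1 each. Cultured pre-cDC1 were wild type (WT), heterozygous for a deletion of the enhancer 32 kb (d32het) or 56 kb (d56het) downstream of the transcription factor gene Irf8, or labelled as the 32 kb deletion without a heterozygous tag (d32). Cultured cDC1 carrying either deletion had been rescued with retroviral IRF8 and were set against WT cDC1 with the empty MSCV retrovirus. Each library used about 1500 to 10000 cells. The design text speaks of biological duplicates while the labels number 3 libraries in most groups, so p-values measure the spread between these libraries, part of which may be technical. Reads carried no molecular identifiers, so floors and counting intervals cover counting error only. Where a group had 0 counts of a gene, the fold is a lower bound from a floor of 3 counts over that group.

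Irf8, the targeted locus, lies on chromosome 8 from 120736358 to 120756694 (GRCm38.p6), and the deletions remove enhancers outside the gene, so its mRNA could be measured in every group. WT pre-cDC1 held 3420 ± 126 CPM (counts scaled to the normalised library total; mean ± SD, n = 3). The level was 1230 ± 116 CPM in d32het (35.9% of WT), 984 ± 98.0 in d56het (28.8%) and 493 ± 37.8 in d32 (14.4%). The 3 WT libraries lay between 3290 and 3550 CPM, and no library of an enhancer-deleted group exceeded 1330. After retroviral rescue, d56 cDC1 held 3620 ± 194 CPM, 101% of the 3580 ± 184 in WT cDC1 with empty vector, while d32 cDC1 held 1340 ± 177 (37.4%). Reads of the retroviral IRF8 cannot be separated from those of the endogenous gene in these counts. Among unmanipulated cells, Irf8 stood at 1480 ± 123 CPM in cultured MDP, 1600 ± 248 in cultured CDP and 752 ± 81.5 in cDC2. Primary cells held 1440 ± 116 in MDP, 1980 ± 709 in bone marrow pre-cDC1 and 2490 ± 515 in splenic pre-cDC1, and the single primary CDP and splenic cDC1 libraries held 3030 and 4310.

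The log2 fold change of Irf8 against WT was -2.80 (SE 0.11, adjusted p = 1.23e-06) in d32, -1.48 (SE 0.10, adjusted p = 0.000249) in d32het and -1.79 (SE 0.10, adjusted p = 1.95e-05) in d56het. After rescue it was 0.01 (SE 0.10, adjusted p = 0.985) in d56 and -1.42 (SE 0.10, adjusted p = 0.000795) in d32. Irf8 was called higher in cultured than in primary bone marrow pre-cDC1 (0.79, SE 0.20, adjusted p = 0.0152). That call was lost with only these 2 groups in the fit (adjusted p = 0.0564), without marrow replicate 1 (0.65, adjusted p = 0.0535) and without marrow replicate 2 (0.67, adjusted p = 0.0622), and over all alternatives the adjusted p lay between 0.00016 and 0.0622. It was not called between cultured CDP and MDP (0.11, SE 0.12, adjusted p = 0.809), between primary pre-cDC1 and MDP (0.45, adjusted p = 0.41) or between spleen and marrow (0.31, adjusted p = 0.686). Irf8 between primary pre-cDC1 and MDP was 0.11 without marrow replicate 3, and between spleen and marrow it was 0.65 without marrow replicate 3, 0.12 without splenic replicate 3, and 0.15 and 0.19 without marrow replicates 1 and 2. Nor was Irf8 called between cultured and primary MDP (1480 ± 123 and 1440 ± 116 CPM, adjusted p = 0.998), between d56het and d32het (-0.30, adjusted p = 0.226), in the interaction of stage and source (0.80, SE 0.28, adjusted p = 0.0905) or between pre-cDC1 and the pre-cDC2 library (0.29, adjusted p = 0.736). The interaction was called for Irf8 by DESeq2 (adjusted p = 0.0468), without marrow pre-cDC1 replicate 3 (1.12, adjusted p = 0.00144) and without replicate 3 of the primary groups, chosen after seeing the data (1.18, adjusted p = 0.00112), with a range of 0.00112 to 0.187 over its alternatives. DESeq2 also called Irf8 lower in d56het than in d32het (adjusted p = 0.0455, range 0.0455 to 0.638 over its alternatives).

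**Figure D1:**
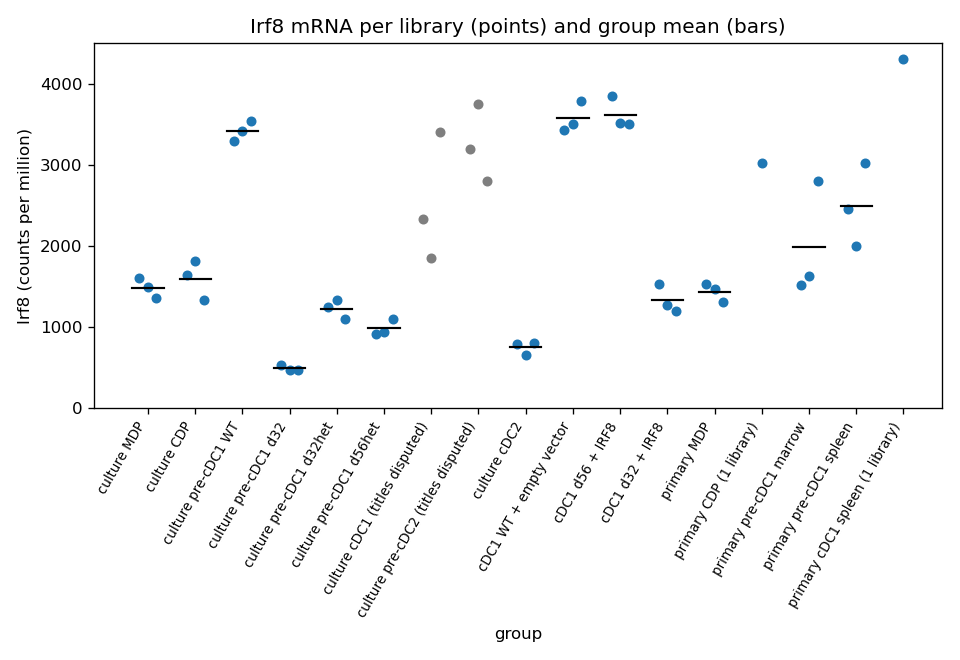
Irf8 level in CPM (linear axis from 0) for each library, by group, with bars at the group mean; groups whose titles and file names disagree carry no bar. The 3 WT pre-cDC1 libraries lie between 3290 and 3550 CPM, and every enhancer-deleted pre-cDC1 library lies at or below 1330.

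Of the genes flanking Irf8 on chromosome 8 (Gse1, Gins2, Emc8, Cox4i1 and others), 6 were measured in the pre-cDC1 and rescue comparisons and edgeR called 0 of them in any of these 8 comparisons. At an unadjusted p under 0.05, 1 of the 6 was higher than WT in each of d32, d32het and d56het, and DESeq2 called 1 in d32 and in d56het and 1 lower in the comparison of the 2 rescued groups. The list median against WT was -0.08 in d32 while the set test pointed upwards.

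The first question was how pre-cDC1 change when the enhancer 32 kb from Irf8 is deleted. Genes that mark the cDC1 lineage fell and genes that mark cDC2 rose in d32 relative to WT pre-cDC1 (3 libraries each). Naaa, a lysosomal acid amidase of the cDC1 signature, fell from 962 ± 122 to 143 ± 16.2 CPM (adjusted p = 2.1e-05). Clec9a, the receptor for actin filaments exposed on dead cells, changed by -3.54 (SE 0.36), and the chemokine receptor gene Xcr1 fell from 40.6 ± 3.19 to 0.983 ± 0.345 CPM. Sirpa, a surface marker of cDC2, rose from 199 ± 10.2 to 1510 ± 183 CPM (2.91, SE 0.15, adjusted p = 1.29e-05), and the transcription factor gene Irf4 rose from 12.1 ± 1.32 to 94.9 ± 23.4 CPM.

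Of 20 measured cDC1 identity genes in d32, 14 fell, 0 rose and 6 were not called (18 lower when adjusted over the list alone). No gene of the list was higher at an unadjusted p under 0.05 or by DESeq2. Rab7b (-1.86, SE 0.21), Ppt1 (-1.02, SE 0.11) and Rab43 (-0.96, SE 0.12) were among those that fell, and the camera test of the list gave an adjusted p of 2.4e-45 (0.000329 with an estimated correlation). Of 15 cDC2 identity genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), among them the fractalkine receptor gene Cx3cr1 (2.51, SE 0.22) and Tmem176a. The plasmacytoid DC (pDC) list moved the same way, with 7 of 16 higher and 1 lower (10 and 1 adjusted over the list alone), including Spib and Tcf4, the latter encoding E2-2, the transcription factor on which pDCs depend. Its camera adjusted p was 7.17e-11 (0.00511 with an estimated correlation). Transcription factors of DCs went both ways: Bcl11a (1.41, SE 0.13) and Cebpa (1.29, SE 0.21) were among 6 of 28 that rose, and Bcl6 (-1.10, SE 0.16) was among 4 that fell (7 and 6 adjusted over the list alone).

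In d32, Cd74, the MHC class II invariant chain, fell from 21700 ± 2090 to 11200 ± 1030 CPM and was the only 1 of 12 class II genes called (3 higher and 2 lower adjusted over the list alone). In the class I and cross-presentation list, the peptide transporter genes Tap1 (-1.24, SE 0.13) and Tap2 (-0.53, SE 0.11) and Tapbp fell, while Cybb, the NADPH oxidase subunit, rose (1.51, SE 0.14; 1 higher and 4 lower adjusted over the list alone, of 16). Immediate early and stress genes gave 1 higher and 6 lower of 18 (1 and 9 adjusted over the list alone), with Nr4a1 (-1.39, SE 0.24) and Fos (-1.05, SE 0.18) lower and Ier3 higher. For this list, the camera adjusted p was 1.39e-06 and p = 0.0637 with an estimated correlation. Cd40 (2.89, SE 0.49) and Ccr7 (2.23, SE 0.39) rose and Cd83 (-2.55, SE 0.49) fell in the DC maturation list (2 and 1 of 19, and 4 and 1 adjusted over the list alone; camera adjusted p = 0.0321, and p = 0.118 with an estimated correlation). Among progenitor genes, Lmo2, Bex6 and Cd93 rose (3 of 17, and 4 adjusted over the list alone; camera adjusted p = 0.000981, and p = 0.034 with an estimated correlation). Monocyte and macrophage genes gave 3 higher (Csf1r, Ms4a6c, Ly6c2) and 1 lower (Lyz2, near the count limit of single-transcript genes) of 17 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0321, and p = 0.224 with an estimated correlation).

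Transcripts of mast cells and basophils were present in the same d32 libraries. Ms4a2, the beta chain of the high-affinity IgE receptor, stood at 95.6 ± 62.3 CPM against 0.629 ± 1.09 in WT, and Fcer1a at 15.9 ± 8.42 against 0.465 ± 0.268. Neither passed the test over all genes (adjusted p = 0.104 and 0.0689); edgeR called 0 of the 5 measured erythroid, mast cell and basophil genes, with 3 higher at an unadjusted p under 0.05, 2 by DESeq2 and 3 adjusted over the list alone (camera adjusted p = 0.00554, and p = 0.118 with an estimated correlation). The genes with the largest rises included Tph1, the peripheral enzyme of serotonin synthesis (49.4 ± 35.6 CPM against 0 counts, at least 1390-fold higher), Slc45a3 (at least 470-fold higher) and Cd200r3 (66.4 ± 45.2 against 0.948 ± 0.394 CPM). Slco2b1 had 3516 counts against 1, a ratio of 3560 with a 95% counting interval of 639 to 141000, and Ctla2a rose by 4.83 (SE 1.11) on the log2 scale. At the other end, Gramd2 was at least 1340-fold lower, with 0 counts in d32. The heat-shock genes Hspa1a (3.23 ± 3.50 against 365 ± 38.9 CPM), Hspa1b and Hspa1l fell as well; Hspa1a and Hspa1b are near-identical copies whose reads the counting could split between them.

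In all, edgeR called 524 of 11604 genes between d32 and WT, 319 higher and 205 lower, and the count lay between 223 and 335 when any 1 of the 6 libraries was left out. Of 49 named genes called, 25 kept the call in every such fit.

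The heterozygous groups show how pre-cDC1 with 1 deleted copy differ from WT. In d32het, cDC2 and pDC genes rose and cDC1 genes fell. Irf4 (76.0 ± 12.6 against 12.1 ± 1.32 CPM), Cx3cr1 (28.8 ± 6.77 against 4.42 ± 0.843 CPM, adjusted p = 0.000293) and Sirpa (1.88, SE 0.15) rose, as did Siglech, a pDC surface lectin (192 ± 43.1 against 40.1 ± 7.68 CPM). Naaa fell to 245 ± 47.6 CPM (-1.98, SE 0.15, adjusted p = 0.000293) and Xcr1 to 5.44 ± 4.80 CPM. Of 20 cDC1 identity genes 8 fell and 0 rose (16 lower adjusted over the list alone; 0 higher at an unadjusted p under 0.05 or by DESeq2; camera adjusted p = 9.42e-19, and 0.00443 with an estimated correlation). Of 15 cDC2 identity genes 13 rose (13 adjusted over the list alone), and of 16 pDC genes 10 rose (13 adjusted over the list alone; camera adjusted p = 4.67e-24, and 0.00051 with an estimated correlation).

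Members of other lists also changed in d32het. Monocyte and macrophage genes gave 4 higher and 1 lower of 17 (4 and 1 adjusted over the list alone), led by Ly6c2 (3.19, SE 0.33), a near copy of Ly6c1 (3.32, SE 0.40). The list gave a camera adjusted p of 0.0172 and p = 0.225 with an estimated correlation. Glycolytic genes Pfkp (-0.68, SE 0.12), Ldha (-0.63, SE 0.11), Gapdh and Pkm fell, 4 of 17 (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00316, and p = 0.424 with an estimated correlation). Immediate early genes Fos (-1.97, SE 0.19) and Nr4a1 (-2.17, SE 0.25) fell with 3 others of 18 (10 adjusted over the list alone; camera adjusted p = 4.26e-11, and p = 0.0211 with an estimated correlation). The largest rises were Kcne3, Ly6c1, Ly6c2, Blnk and Clec4a3, between 3.09 and 3.52 on the log2 scale. The largest falls were Gramd2 (4071 counts against 1, ratio 4040, 95% counting interval 726 to 160000), Hspa1b, Hspa1a, Phlda1 and Cd83. The Y-linked genes Uty (1.01, SE 0.22) and Eif2s3y (0.66, SE 0.14) were higher in d32het than in WT, 2 of the 4 sex-linked genes measured (2 adjusted over the list alone; camera adjusted p = 0.0273, and p = 0.123 with an estimated correlation). In all, 431 genes were called, 268 higher and 163 lower. The count lay between 135 and 369 when any 1 of the 6 libraries was left out, and was 184 with only these 2 groups in the fit, where the balance turned to 85 higher and 99 lower. Among 49 named genes called, 26 kept the call in every fit that left out 1 library.

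In d56het pre-cDC1, cDC1 genes fell and pDC and cDC2 genes rose relative to WT. Tcf4 rose from 300 ± 70.0 to 1820 ± 305 CPM (log2 fold change 2.61, SE 0.19, adjusted p = 3.58e-05), Siglech to 350 ± 145 CPM and Atp1b1 by 4.69 (SE 0.40). Rab7b, a GTPase of the endolysosomal pathway, fell from 1150 ± 73.1 to 121 ± 29.9 CPM (-3.24, SE 0.22), Naaa to 106 ± 4.45 CPM and Cd74 to 6100 ± 815 CPM (-1.82, SE 0.16). Irf4 (3.25, SE 0.23), Sirpa (2.62, SE 0.15), Ly6c2 (3.71, SE 0.34) and Cd14 (1.95, SE 0.24) rose.

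By list, 16 of 20 cDC1 identity genes fell (19 adjusted over the list alone; none rose by edgeR, DESeq2 or at an unadjusted p under 0.05), 14 of 15 cDC2 identity genes rose (14 adjusted over the list alone) and 13 of 16 pDC genes rose (15 adjusted over the list alone). The camera adjusted p was 5.68e-35, 4.38e-33 and 8.05e-29 for these lists, and 0.000896, 0.000457 and 0.000457 with an estimated correlation. Replication genes Mcm6 (-0.93, SE 0.09), Mcm7 (-0.88, SE 0.11), Mcm5 and Mki67 were among 6 of 21 cell cycle genes that fell (2 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.014, and p = 0.528 with an estimated correlation). Class II genes gave 1 higher (Ifi30) and 5 lower of 12 (2 and 6 adjusted over the list alone), with Ciita, the class II transactivator, at 747 ± 35.4 against 1340 ± 62.1 CPM. For this list, the camera adjusted p was 0.00267 and p = 0.31 with an estimated correlation. Monocyte and macrophage genes gave 4 higher (Ly6c2, Cd14, Csf1r and Ms4a6c) and 1 lower (Lyz2) of 17 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00369, and p = 0.156 with an estimated correlation). Tap1 (-1.74, SE 0.13), Tap2 and Tapbp fell and Cybb (2.03, SE 0.14) rose. Glycolytic genes gave 5 lower of 17 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.000903, and p = 0.31 with an estimated correlation). Among progenitor genes Kit (-1.98, SE 0.24) and Cd34 (-2.96, SE 0.35) fell while Lmo2 and Bex6 rose (5 higher and 2 lower of 17, the same counts adjusted over the list alone). Uty (1.36, SE 0.22) and Eif2s3y (0.55, SE 0.14) were again higher than in WT (2 of 4, and 2 adjusted over the list alone).

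Several genes with large changes in d56het had no counts in 1 group. Tlr7, Zcchc18 and Kcng1 were at least 631-fold, 644-fold and 365-fold higher than in WT, and Sema4f, Gramd2, the integrin gene Itgae (CD103), Cd226 and Rnf180 were at least 2860-fold, 1330-fold, 927-fold, 401-fold and 308-fold lower. Cmah and Tbxa2r also rose. The comparison called 1438 genes, 710 higher and 728 lower. The count lay between 793 and 1261 when any 1 of the 6 libraries was left out, and 51 of the 64 named genes called kept the call in every such fit.

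**Figure D2:**
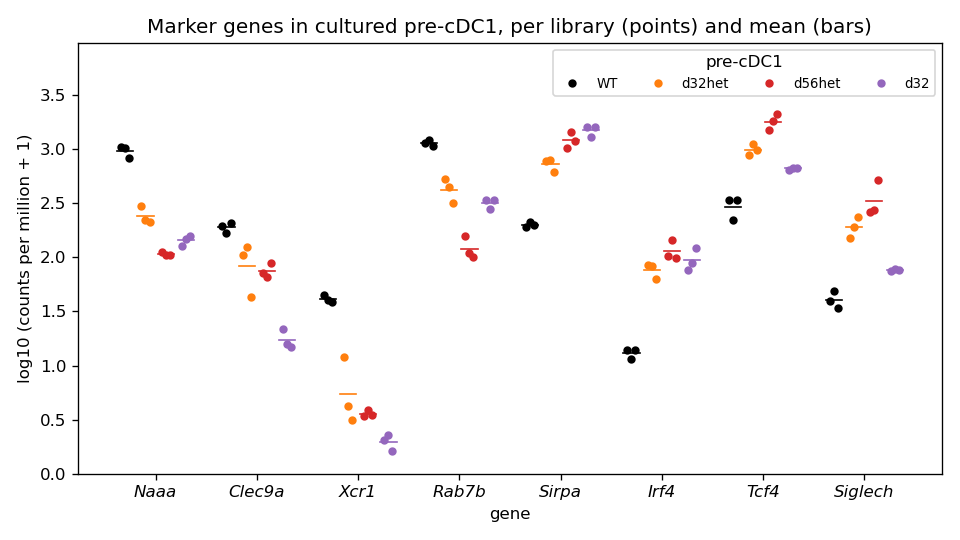
CPM of 8 marker genes (log10 of CPM + 1) in each of the 12 cultured pre-cDC1 libraries, by genotype, with bars at the group mean of the plotted values. Naaa, Clec9a, Xcr1 and Rab7b are lower in the enhancer-deleted groups than in WT, and Sirpa, Irf4, Tcf4 and Siglech are higher.

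All 390 genes called in both d32het and d56het moved in the same direction, 249 higher and 141 lower, where independent lists would share 16.4 and 10.2. Unchanged groups simulated against shared, redrawn WT libraries called a median of 0 genes, so their overlap of at most 1 decides nothing. The covariance of log2 fold changes was 1.49 (simulated mean 0.531, highest 0.593). The d32 and d32het groups shared 282 calls, all in the same direction (180 higher, 102 lower; independent lists, 7.37 and 2.88). Their covariance was 1.02 against a simulated 0.545, and their correlation of 0.497 was no higher than the 0.508 that shared controls alone give. The 3 WT libraries were not divided between the comparisons, since 1 part would hold a single library, so part of each excess may come from them.

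Among the deleted groups, d32 was first compared with d32het. Clec9a (16.5 ± 3.92 against 89.7 ± 42.2 CPM; -2.44, SE 0.35, adjusted p = 0.0433) and Irf8 (-1.32, SE 0.10) were lower in d32 than in d32het. Sirpa (1.03, SE 0.14), Lmna (2.14, SE 0.28) and the cytokine receptor genes Csf2rb and Csf2rb2, near copies of each other, were higher, and Rtl8b was lower. The test called 8 genes, 4 in each direction, and between 1 and 8 when any 1 of the 6 libraries was left out; 1 call was left with only these 2 groups in the fit, in which Irf8 had an adjusted p of 0.088 (range 1.59e-33 to 0.088 over its alternatives). Of 20 cDC1 identity genes 1 was lower (9 adjusted over the list alone; camera adjusted p = 2.62e-15, and 0.0186 with an estimated correlation). Of 16 pDC genes edgeR called 0, with 5 lower at an unadjusted p under 0.05, 2 lower by DESeq2 and 3 lower adjusted over the list alone (camera adjusted p = 1.21e-06, and p = 0.022 with an estimated correlation). Interferon-stimulated genes gave 0 of 16 in edgeR and 0 adjusted over the list alone, with 3 higher at an unadjusted p under 0.05 and 2 by DESeq2 (camera adjusted p = 0.000129, and p = 0.0186 with an estimated correlation).

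The 2 heterozygous groups were then compared. Ifi205 (-1.10, SE 0.13), Rab7b (-1.82, SE 0.21), Naaa (-1.20, SE 0.15) and Rab43 were lower in d56het than in d32het, as were Ciita (-0.87, SE 0.12), Bcl6 (-1.02, SE 0.16), Kit (-1.67, SE 0.24) and Cd34. Atp1b1 (29.0 ± 3.15 against 6.99 ± 2.65 CPM), Fos, Slc39a10 and Hmgn3 were higher; Kcng1 was at least 362-fold higher, and Sema4f and Cd226 at least 425-fold and 278-fold lower. Of 20 cDC1 identity genes 5 were lower (12 adjusted over the list alone; camera adjusted p = 2.76e-22, and 0.0106 with an estimated correlation), and of 16 pDC genes 1 was higher (9 adjusted over the list alone; camera adjusted p = 6.27e-10, and 0.0114 with an estimated correlation). Clspn, Gatm, Atad5 and Mcm7 were also lower and H2bc4 higher. edgeR called 61 genes, 12 higher and 49 lower, with a range of 39 to 67 when any 1 of the 6 libraries was left out. With only these 2 groups in the fit edgeR called 0, with 839 at an unadjusted p under 0.05; DESeq2 called 697.

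The rescue asked how cDC1 that lack an enhancer but carry retroviral IRF8 compare with WT cDC1. In d56 cDC1 with IRF8, Xcr1 was 69.6 ± 4.38 against 68.8 ± 1.82 CPM (log2 fold change 0.01, SE 0.09, adjusted p = 0.99). Itgae (263 ± 20 against 103 ± 18.7; 1.35, SE 0.15, adjusted p = 0.00477) and the adhesion molecule gene Cadm1 (0.69, SE 0.11) were higher. Cd83 (0.95, SE 0.08, adjusted p = 0.00121) and the NF-kB subunit gene Relb (0.95, SE 0.16) rose. Only these 2 of 20 maturation genes passed over all genes, and 12 rose when adjusted over the list alone (camera adjusted p = 2.9e-13, and 0.00886 with an estimated correlation). Of 15 cDC2 identity genes 2 rose, Itgam and Tmem176b (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.23e-05, and p = 0.111 with an estimated correlation).

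Mki67 (-0.65, SE 0.11) and Aurka fell in d56 with IRF8, 2 of 21 cell cycle genes (7 adjusted over the list alone; camera adjusted p = 4.5e-07, and p = 0.22 with an estimated correlation). Interferon-stimulated genes gave 1 higher of 18, Ifit1 (at least 78.8-fold), and 8 adjusted over the list alone (camera adjusted p = 5.36e-13, and p = 0.111 with an estimated correlation). Monocyte and macrophage genes gave Ly6c2 higher and Ccr2 lower of 19 (10 and 2 adjusted over the list alone; camera adjusted p = 6.73e-05, and p = 0.111 with an estimated correlation). The largest rises were Ndrg4, Rgs9 and Arhgef10l, at least 865-fold, 767-fold and 336-fold from 0 counts, then Cables1 (78.7 ± 15.4 against 3.11 ± 2.18 CPM) and Slc7a7. The largest falls were Cyp11a1 (-2.03, SE 0.40), Cd22, Pif1, Clec4b1 and Cdkn3. The comparison called 192 of 11620 genes, 142 higher and 50 lower, and 55 to 95 when any 1 of the 6 libraries was left out.

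In d32 cDC1 with IRF8, whose Irf8 mRNA was at 37.4% of WT, cDC2 genes rose. Tmem176b (725 ± 39.4 against 160 ± 23.5 CPM; 2.17, SE 0.17, adjusted p = 0.00123), Tmem176a (1.62, SE 0.13), Cd300a (1.22, SE 0.11), Itgam, Cd7 (2.65, SE 0.41) and Sirpa (292 ± 113 against 45.4 ± 21.5 CPM) were the 6 of 15 higher (12 adjusted over the list alone; camera adjusted p = 3.13e-24, and 0.0113 with an estimated correlation). Tlr11 (-0.87, SE 0.13), Btla and Cadm1 (-0.57, SE 0.11) fell and Itgae (1.38, SE 0.15) rose among 22 cDC1 identity genes (2 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.018, and p = 0.177 with an estimated correlation). Interferon-stimulated genes gave 5 higher of 18 (12 adjusted over the list alone), including Zbp1 (28.0 ± 1.04 against 6.49 ± 3.21 CPM), Ifit2, Usp18 (0.84, SE 0.16), Ifit1 (at least 160-fold) and Oasl2. The list gave a camera adjusted p of 1.3e-15 and p = 0.0842 with an estimated correlation. Adgre1, the macrophage antigen F4/80, and Trem2 rose, 2 of 19 monocyte and macrophage genes (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00104, and p = 0.142 with an estimated correlation). Fdps was among 2 of 15 cholesterol synthesis genes that fell (3 adjusted over the list alone; camera adjusted p = 0.00328, and p = 0.311 with an estimated correlation). Ndrg4 was at least 654-fold higher, and Il21r (3.53, SE 0.36) and Slc7a7 rose, while Tcf20, Kat8, Dusp7 and Cd226 fell. In all 241 genes were called, 131 higher and 110 lower (82 to 143 when any 1 of the 6 libraries was left out; 81 with only these 2 groups in the fit). The rescued groups shared 51 calls, 50 of them in the same direction (45 higher, 5 lower; independent lists, 1.6 and 0.473). Their covariance was 0.925 against a simulated 0.288 (highest 0.333). Part of the excess may come from the shared WT libraries or from the retroviral IRF8 that both rescued groups carry.

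Set directly against each other, d56 with IRF8 held more Irf8 (1.44, SE 0.10), Cadm1 (1260 ± 107 against 525 ± 61.1 CPM), Tlr11, Gcsam and Cd83 (0.68, SE 0.08) than d32 with IRF8, and less Cd300a (-1.64, SE 0.11), Tmem176a, Tmem176b and Bcl11a. Of 22 cDC1 identity genes 3 were higher (7 adjusted over the list alone; camera adjusted p = 5.79e-05) and of 15 cDC2 identity genes 3 were lower (3 adjusted over the list alone; camera adjusted p = 4.26e-11), each with p = 0.0458 with an estimated correlation. Gapdh was higher, 1 of 17 glycolytic genes (8 adjusted over the list alone; camera adjusted p = 2.26e-10, and p = 0.187 with an estimated correlation). Cables1 (3.54, SE 0.45), Rgs9, Treml4, Fndc5 and Serpinb6b were the largest differences upwards, and Ceacam2, Slc52a3, Cd22, Ceacam1 and Mcoln2 downwards. The comparison called 122 genes, 72 higher and 50 lower (33 to 97 when any 1 of the 6 libraries was left out).

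The WT cultures gave the course of development. From MDP to CDP the stem cell factor receptor gene Kit fell from 189 ± 20 to 27.6 ± 10.9 CPM (log2 fold change -2.78, SE 0.22, adjusted p = 0.000103), Myc fell by 1.36 (SE 0.17) and Cd34 fell by 1.27 (SE 0.18). Siglech rose from 53.3 ± 0.801 to 181 ± 19.8 CPM (1.76, SE 0.26) and Klf4 rose by 1.04 (SE 0.18). Rab7b (-1.47, SE 0.11), Tlr3 (9.86 ± 3.41 to 0.193 ± 0.335 CPM) and Naaa were among 7 of 22 cDC1 identity genes that fell (8 adjusted over the list alone; camera adjusted p = 8.44e-10, and 0.00152 with an estimated correlation). Of 20 stem and progenitor genes 3 fell (4 adjusted over the list alone; camera adjusted p = 7.55e-05, and p = 0.0236 with an estimated correlation), and of 18 pDC genes 2 rose (10 adjusted over the list alone; camera adjusted p = 6.95e-10, and 0.00116 with an estimated correlation). Hrh1 (25.8 ± 13 against 0.645 ± 1.12 CPM), Ddr1, Lilrb4a and Atp1b1 rose most, and Mgst1, Cd63, Gcsam and Tbc1d9 fell. The test called 138 of 13292 genes, 81 higher and 57 lower (61 to 105 when any 1 of the 6 libraries was left out; 26 with only these 2 groups in the fit).

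From CDP to pre-cDC1, genes of the cDC1 program and of antigen presentation rose, and most of the called progenitor and pDC genes fell. Naaa rose from 26.2 ± 4.22 to 962 ± 122 CPM (5.20, SE 0.20, adjusted p = 3.56e-09), Rab7b by 4.39 (SE 0.12), Cd74 from 1000 ± 281 to 21700 ± 2090 CPM (4.44, SE 0.18) and Cd83 by 6.20 (SE 0.24). Irf8 itself rose by 1.10 (SE 0.12), Bcl6 by 1.89 (SE 0.13) and Id2, the HLH factor required for cDC1, by 1.27 (SE 0.10); Id2 lies near the count limit of single-transcript genes. Of 22 cDC1 identity genes 19 rose (20 adjusted over the list alone; camera adjusted p = 2.91e-24, and 0.000201 with an estimated correlation). Of 12 class II genes 11 rose (12 adjusted over the list alone; camera adjusted p = 3.16e-19, and 0.0116 with an estimated correlation), with H2-DMb2 (2.63, SE 0.08), Ciita (3.30, SE 0.15) and H2-DMb1 among them. Class I genes gave 9 higher, among them Tap1 (1.94, SE 0.07), H2-D1 and Tapbp, and 1 lower of 16 (10 and 1 adjusted over the list alone; camera adjusted p = 6.03e-05, and p = 0.107 with an estimated correlation).

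In the same step 10 of 18 pDC genes fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 1.83e-05, and 0.0116 with an estimated correlation), including Tcf4 (-1.70, SE 0.17), Siglech (-2.17, SE 0.26), Runx2 and Dntt (at least 146-fold lower). Of 20 progenitor genes 11 fell and 3 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.000865, and p = 0.0257 with an estimated correlation), with Cd93 (-1.95, SE 0.17) and Cdk6 lower and Kit higher again (3.36, SE 0.23). Granule genes gave 8 lower and 2 higher of 18 (8 and 5 adjusted over the list alone; camera adjusted p = 0.0601), Ctsg at 1802 counts against 1 (ratio 1650, 95% counting interval 296 to 65200) and Csf3r at least 332-fold lower. Immediate early and stress genes rose, 11 of 18 with 1 lower (12 and 1 adjusted over the list alone), Fos by 3.17 (SE 0.38), Junb by 1.23 (SE 0.13) and Hspa1b by 6.62 (SE 1.04). For this list, the camera adjusted p was 1.01e-05 and p = 0.0525 with an estimated correlation. Cholesterol synthesis genes rose in 7 of 15 (8 adjusted over the list alone), among them Hmgcs1 (1.24, SE 0.16). The list gave a camera adjusted p of 2.97e-05 and p = 0.166 with an estimated correlation. Replication genes such as Mcm7 (-0.97, SE 0.10) fell in 9 of 21 (14 adjusted over the list alone; camera adjusted p = 1.34e-05, and p = 0.263 with an estimated correlation). Sema4f, Gramd2, Dapk2, Itgae and Wnt11 rose from 0 counts by at least 3190-fold, 1480-fold, 1120-fold, 1030-fold and 965-fold. Muc13, Myl10, Kcng1, Fgd4 and Emid1 fell to 0 counts by at least 2570-fold, 1540-fold, 1170-fold, 478-fold and 443-fold. The test called 3101 genes, 1614 higher and 1487 lower, and 71 of the 78 named genes called kept the call when any 1 of the 6 libraries was left out.

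Between the mature subsets, empty-vector cDC1 and cDC2 differed in their identity genes and in the cell cycle. Irf8 was 3580 ± 184 CPM in cDC1 against 752 ± 81.5 in cDC2 (adjusted p = 2.3e-07), and Xcr1 was higher in cDC1 by 3.95 (SE 0.42). Sirpa (45.4 ± 21.5 against 3960 ± 482 CPM; -6.44, SE 0.35), Tmem176b (-4.21, SE 0.19) and Csf1r (-3.11, SE 0.31) were lower in cDC1. Of 22 cDC1 identity genes 19 were higher (19 adjusted over the list alone) and of 15 cDC2 identity genes 13 were lower (13 adjusted over the list alone), with camera adjusted p of 2.8e-19 and 4.16e-19 (7.65e-05 and 0.00103 with an estimated correlation). All 21 cell cycle genes were higher in cDC1 (21 adjusted over the list alone), Tyms by 0.97 (SE 0.10) and Mki67 by 0.96 (SE 0.14). For this list, the camera adjusted p was 5.33e-15 and p = 0.0601 with an estimated correlation. Maturation genes were lower in cDC1 in 11 of 21 and higher in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 4.64e-07, and 0.00271 with an estimated correlation), led by Ccr7 (-7.39, SE 0.89) and Relb (-1.61, SE 0.20). Of 18 pDC genes 13 were lower (15 adjusted over the list alone; camera adjusted p = 3.35e-14, and 0.000223 with an estimated correlation), with Siglech (-4.42, SE 0.29) and Spib (-6.48, SE 0.71). Monocyte and macrophage genes gave 11 lower and 1 higher of 21 (11 and 1 adjusted over the list alone; camera adjusted p = 3.76e-06, and p = 0.0477 with an estimated correlation). Dkk3, Ccser1 and Lrrc3 were at least 523-fold, 362-fold and 341-fold higher, and Naalad2 and Ttc39a also higher; Ccr6, Gria3, Mtus1, Scn3a and Pacsin1 were at least 3510-fold, 2510-fold, 1690-fold, 920-fold and 881-fold lower. The comparison called 2411 genes, 1209 higher and 1202 lower. The empty-vector cDC1 had gone through retroviral transduction and cDC2 had not, so subset and handling were not separated.

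Titles and file names disagree for replicates 1 and 2 of the untransduced cDC1 and of pre-cDC2, so the comparisons of these groups with pre-cDC1 used replicate 3 alone, assumed to vary like the other groups. In the cDC1 library, Dusp6 (31.5 CPM against 3.63 ± 0.551), Myc (654 against 108 ± 18.1), Trim34a, Kbtbd11 and Ier3 were higher than in pre-cDC1, and Id3 (-6.47, SE 0.95) and Fmnl3 lower. Hspa1a and Hspa1l were at least 3750-fold and 378-fold lower, and Hspa1b had 29376 counts against 1 (ratio 11000, 95% counting interval 1970 to 434000). Glycolytic genes Slc2a1 (1.59, SE 0.19), Pfkl, Hk2 and Pdk1 were among 5 of 18 that were higher (10 adjusted over the list alone; camera adjusted p = 7.23e-09, and p = 0.311 with an estimated correlation). Mcm2, Mcm6 and 4 others of 21 cell cycle genes were lower (8 adjusted over the list alone; camera adjusted p = 0.000307, and p = 0.429 with an estimated correlation). The test called 301 genes, 134 higher and 167 lower, or 158 higher of 281 with DESeq2 size factors. The count was 135 to 206 when any 1 of the pre-cDC1 libraries was left out, 3 with only these libraries in the fit and 23 with all libraries kept under their titles. Against the pre-cDC2 library, pre-cDC1 had less Cebpb (-2.86, SE 0.31, adjusted p = 0.00454), Mgst1, Sdc1, Fcgr3, Ly6c1, Ly6c2 and Anxa3 and at least 495-fold less Csf3r, and more Cd34 and Trim32. Monocyte and macrophage genes were lower in 3 of 21 (11 adjusted over the list alone; camera adjusted p = 6.45e-17, and 0.00582 with an estimated correlation). The test called 20 genes, 4 higher and 16 lower (13 to 23 when any 1 of the pre-cDC1 libraries was left out), 0 with only these libraries in the fit (1041 at an unadjusted p under 0.05; 273 by DESeq2) and 1 under the titles.

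In primary bone marrow, pre-cDC1 differed from MDP in lineage, presentation and progenitor genes. Clec9a rose from 10.1 ± 2.94 to 207 ± 34.0 CPM (4.34, SE 0.32, adjusted p = 0.000442), Zbtb46, a transcription factor of conventional DCs, by 4.87 (SE 0.38) and Batf3, which cDC1 require, from 0.380 ± 0.143 to 5.73 ± 1.60 CPM. Cd34 fell from 827 ± 107 to 57.9 ± 3.68 CPM (-3.85, SE 0.17) and Kit from 269 ± 62.8 to 29.2 ± 6.87 CPM. Irf4 of the cDC2 list (56.9 ± 13.1 CPM) and Bhlhe40 (44.5 ± 5.23 CPM) rose from 0 counts in MDP, at least 2170-fold and 1640-fold. Irf7 rose by 4.38 (SE 0.40). Of 22 cDC1 identity genes 7 rose (7 adjusted over the list alone; camera adjusted p = 6.69e-05, and p = 0.143 with an estimated correlation), of 15 cDC2 identity genes 6 (8 adjusted over the list alone; camera adjusted p = 0.000227, and p = 0.0331 with an estimated correlation) and of 19 pDC genes 7 (10 adjusted over the list alone; camera adjusted p = 6.85e-05, and p = 0.191 with an estimated correlation).

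Class II genes rose in 8 of 12 (11 adjusted over the list alone), with Ctss (2.01, SE 0.16) and Ifi30 (2.74, SE 0.36). The list gave a camera adjusted p of 5.23e-08 and p = 0.0587 with an estimated correlation. Cholesterol synthesis genes rose in 6 of 15 (10 adjusted over the list alone), among them Fdft1 (1.52, SE 0.21) and Mvd (2.52, SE 0.42). For this list, the camera adjusted p was 5.66e-06 and p = 0.0331 with an estimated correlation. Interferon-stimulated genes rose in 4 of 18 (6 adjusted over the list alone; camera adjusted p = 0.00014, and p = 0.0639 with an estimated correlation). Of 20 progenitor genes 7 fell (9 adjusted over the list alone; camera adjusted p = 6.84e-06, and p = 0.0331 with an estimated correlation). Hrh1, Prr5l and the granule protein gene Ltf were at least 6830-fold, 2700-fold and 959-fold higher, and Rapgef3, Tctex1d1, Ak4 and Zfp618 at least 788-fold, 629-fold, 534-fold and 329-fold lower, with Il1r1 lower too. The test called 1085 of 13161 genes, 738 higher and 347 lower (455 to 794 when any 1 of the 6 libraries was left out; 3188 with only these 2 groups in the fit).

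Splenic and bone marrow pre-cDC1 differed in cDC1 genes, immediate early genes and proliferation. Tlr3 was 225 ± 63.6 CPM in spleen against 4.31 ± 2.69 in marrow (5.68, SE 0.69, adjusted p = 0.0189), Rab7b 484 ± 41.4 against 49.6 ± 22.0, Fos 86.9 ± 27.6 against 4.60 ± 0.157 and Egr1 53.3 ± 22.0 against 1.18 ± 0.414. Top2a was 26.8 ± 10 against 155 ± 21.8 CPM (-2.54, SE 0.30). Of 22 cDC1 identity genes 7 were higher (16 adjusted over the list alone; camera adjusted p = 2.35e-15, and p = 0.0375 with an estimated correlation), of 18 immediate early and stress genes 7 (8 adjusted over the list alone; camera adjusted p = 3.61e-10, and 0.00784 with an estimated correlation) and of 12 class II genes 4 (8 adjusted over the list alone; camera adjusted p = 8.26e-10, and p = 0.0375 with an estimated correlation), H2-Ob by 3.07 (SE 0.32). Cell cycle genes were lower in 10 of 21 (18 adjusted over the list alone), Ccna2 by -2.12 (SE 0.24) and Birc5 by -2.88 (SE 0.36). The list gave a camera adjusted p of 3.2e-16 and p = 0.076 with an estimated correlation. Granule genes were lower in 5 of 18 (11 adjusted over the list alone; camera adjusted p = 3.81e-10, and p = 0.0152 with an estimated correlation), Ctsg and Ltf at least 45.3-fold and 540-fold, and F13a1 (-4.11, SE 0.45), Cebpb, Ly6c2 and Fn1 were lower among 21 monocyte and macrophage genes (1 higher and 5 lower adjusted over the list alone). That list's median was -0.10 and its mean 0.04, with the set test pointing downwards (adjusted p = 0.351). Kit was higher (3.48, SE 0.49), and Traf1, Gpr141b (1192 counts against 2, ratio 658, 95% counting interval 182 to 5430) and Gcsam (7540 against 1, ratio 8320, 1490 to 329000) were among the largest rises. Cacna1d, Ly6a2 and Papss2 were at least 309-fold, 221-fold and 208-fold lower, and Chdh had 5006 counts in marrow against 1 (ratio 4540, 95% counting interval 814 to 179000).

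Splenic pre-cDC1 replicates 1 and 2 (10009 and 9901 genes detected) correlated less with each other (0.81) than with replicate 3 (0.86 and 0.83). Replicate 3 (11826 genes) held 296 CPM of Cadm1 against 0.0593 and 0, and 38.0 of Xcr1 against 0.889 and 5.24. Cadm1 was not called between spleen and marrow (3.70, adjusted p = 0.57) and was called lower without replicate 3 (adjusted p = 0.00299). Spleen against marrow gave 247 genes, 79 higher and 168 lower, and 1152 without splenic replicate 3 (68 to 1152 with 1 library left out). Without replicate 3 of all primary groups, chosen after seeing the data, 593 were called, 155 of them shared.

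Culture was compared with primary cells at both stages. Cultured MDP held more cDC1, class II, cholesterol and stress-response genes than primary MDP. Ifi205 was higher by 2.19 (SE 0.15, adjusted p = 1.59e-05), Batf3 by 3.96 (SE 0.35), Cd74 by 5.29 (SE 0.64) and Ddit3, a gene of the integrated stress response, by 3.69 (SE 0.27). Of 21 cDC1 identity genes 12 were higher (13 adjusted over the list alone; camera adjusted p = 1.45e-16, and 0.00025 with an estimated correlation), of 15 cholesterol synthesis genes 14 (14 adjusted over the list alone; camera adjusted p = 4.58e-24, and 0.000566 with an estimated correlation), including Fdps (1.06, SE 0.10) and Cyp51, of 12 class II genes 11 (12 adjusted over the list alone; camera adjusted p = 2.99e-18, and 0.00598 with an estimated correlation) and of 18 immediate early and stress genes 7 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.49e-15, and 0.00025 with an estimated correlation). Glycolytic genes gave 7 higher of 17 (10 adjusted over the list alone; camera adjusted p = 5.05e-06, and p = 0.164 with an estimated correlation). Cd34 (-1.14, SE 0.19) and Myc were lower among 18 progenitor genes (2 adjusted over the list alone; camera adjusted p = 0.00248, and p = 0.101 with an estimated correlation). Thbs1, Il1r2, Trib3, Chac1 and Cd83 were at least 9860-fold, 4830-fold, 1260-fold, 829-fold and 778-fold higher, and Dclk2 and Ets1 at least 527-fold and 409-fold lower, with Chdh (-6.13, SE 1.05), Cacna1d and Fgf13 lower. The globin genes Hba-a1 and Hba-a2, near-identical copies, were at least 240-fold and 232-fold lower in culture. The test called 997 of 12043 genes, 648 higher and 349 lower (585 to 852 when any 1 of the 6 libraries was left out).

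Cultured pre-cDC1 held more cDC1 and less cDC2, pDC and granule gene mRNA than primary bone marrow pre-cDC1. Rab7b was higher by 4.54 (SE 0.31, adjusted p = 1.29e-05), Wdfy4, needed for cross-presentation by cDC1, by 2.01 (SE 0.18), Fos by 3.55 (SE 0.14), Kit by 3.28 (SE 0.21) and Aldoa by 2.60 (SE 0.22), while Cx3cr1 (-4.31, SE 0.32), Sirpa (-2.23, SE 0.22), Cebpb (-2.53, SE 0.16), Ly6c2 (-5.69, SE 0.42) and Runx2 (-3.75, SE 0.33) were lower. Of 21 cDC1 identity genes 17 were higher (19 adjusted over the list alone; camera adjusted p = 6.8e-21, and 0.000107 with an estimated correlation); of 15 cDC2 identity genes 9 were lower (9 adjusted over the list alone; camera adjusted p = 4.53e-05, and 0.012 with an estimated correlation). Of 17 pDC genes 11 were lower (13 adjusted over the list alone; camera adjusted p = 1.49e-08, and 0.0131 with an estimated correlation) and of 18 granule genes 8 (9 adjusted over the list alone; camera adjusted p = 7.9e-09, and p = 0.0303 with an estimated correlation). Immediate early and stress genes were higher in 12 of 18 (14 adjusted over the list alone; camera adjusted p = 7.8e-15, and 0.000232 with an estimated correlation), glycolytic genes in 10 of 17 (12 adjusted over the list alone; camera adjusted p = 1.11e-09, and p = 0.0679 with an estimated correlation) and cholesterol synthesis genes in 9 of 15 (12 adjusted over the list alone; camera adjusted p = 1.8e-08, and 0.013 with an estimated correlation). Htr7, Sema6d, Scin and Rasgrp3 were at least 9430-fold, 4870-fold, 4580-fold and 1620-fold higher and Gcsam had 19554 counts against 1 (ratio 16100, 95% counting interval 2890 to 637000). Chdh, Abca9, Pde2a, Hba-a1 and Hba-a2 were at least 2020-fold, 947-fold, 798-fold, 743-fold and 727-fold lower. The globin genes Hbb-bt and Hbb-bs were at least 222-fold and 215-fold lower, so red cell transcripts moved with the primary group. The test called 2634 genes, 1283 higher and 1351 lower.

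Whether the step from MDP to pre-cDC1 itself differed between culture and bone marrow was tested as an interaction. Kit fell in marrow (269 ± 62.8 to 29.2 ± 6.87 CPM) and stood at 189 ± 20 and 284 ± 13.3 CPM in culture, a difference between the steps of 3.84 (SE 0.29, adjusted p = 9.88e-05). Cd7 went from 1.15 ± 0.666 to 46.9 ± 9.91 CPM in marrow and from 14.9 ± 1.20 to 18.6 ± 2.01 in culture (-4.95, SE 0.45), and Cx3cr1 from 29.7 ± 5.11 to 88.0 ± 31.1 and from 20.2 ± 3.93 to 4.42 ± 0.843 (-3.70, SE 0.40). Among the genes with the largest differences, Rasgrp3 reached 71.3 ± 12.9 CPM and Scin 204 ± 30.7 CPM in cultured pre-cDC1 against 0 counts in marrow pre-cDC1, while Irf4 stood at 12.1 ± 1.32 against 56.9 ± 13.1, Bhlhe40 at 21.8 ± 3.95 against 44.5 ± 5.23 and Kcng1 at 0 counts against 12.4 ± 4.40. Sema4f reached 109 ± 59.9 CPM and Gcsam 240 ± 47.7 in cultured pre-cDC1, against means of 0.0198 and 0.0172 CPM in marrow pre-cDC1. Ptger3 was 70.2 ± 6.30 against 0.103, and Myl10 and Fgd4 went from 79.2 ± 12.4 and 41.4 ± 6.23 CPM in cultured MDP to 0 counts in cultured pre-cDC1, and from 0.464 to 0.217 and 25.1 to 14.7 CPM in marrow. Of 15 cDC2 identity genes 7 had a lower step in culture (9 adjusted over the list alone; camera adjusted p = 7.99e-10, and 0.00213 with an estimated correlation), of 17 pDC genes 8 (14 adjusted over the list alone; camera adjusted p = 2.29e-09, and 0.0124 with an estimated correlation) and of 28 DC transcription factors 12, with 2 higher (13 and 4 adjusted over the list alone; camera adjusted p = 9.92e-05, and 0.0124 with an estimated correlation). Granule genes gave 5 lower of 18 (7 adjusted over the list alone; camera adjusted p = 2.83e-06, and p = 0.14 with an estimated correlation). The cDC1 identity list gave 7 higher (Snx22, Rab7b, Ppt1, Xcr1 and others) and 2 lower (Batf3, -2.46, SE 0.44, and Clec9a, -1.97, SE 0.36) of 21 (7 and 4 adjusted over the list alone; camera adjusted p = 0.0873, and p = 0.216 with an estimated correlation). The interaction was called in 1376 genes, 576 higher and 800 lower. The count was 861 to 1893 when any 1 of the 12 libraries was left out, and 2409, 1227 of them shared, without replicate 3 of the primary groups, an alternative chosen after seeing the data.

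Single libraries without a replicate check completed the primary series. The primary CDP library held 53.0 CPM of Kit, 251 of Cd34, 107 of Siglech and 0.870 of Xcr1. The primary splenic cDC1 library held 83.3 CPM of Xcr1, 2880 of Cadm1, 1520 of Naaa and 44700 of Cd74, with 25.5 of Sirpa and 0 counts of Irf4.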

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

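The tests of gene length, of a strain difference and of correlation with the empty-vector libraries were chosen only after the result was seen, as was the choice of the 10 genes of fixed lists given for culture against bone marrow.

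The step from MDP to pre-cDC1 differed between culture and bone marrow in 1376 genes, by a test of the interaction. Among members of the fixed lists with more than 3 counts in all 4 groups, the 10 with the smallest adjusted p were Kit (3.84 on the log2 scale, culture minus marrow), Cd7 (-4.95), Fos (1.98), Klf4 (-3.69), Cybb (-2.65), Snx22 (1.72), Cx3cr1 (-3.70), Runx2 (-3.66), Nfil3 (2.55) and Tap1 (1.34). Of 100 splits of the 12 libraries, 2 gave as many genes, the real one included. The other called 5083 genes, several times the real count, and exchanges MDP and pre-cDC1 within 1 source, which is a structure of the samples. These 2 are also the only ones drawn that keep each stage whole, too few for a share under 0.05, and the other splits mix the stages within a group.

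The libraries labelled FL cDC1 replicates 1 and 2, compared in the report only when kept under their titles, held 363 and 385 CPM of Hspa1a, against 0 in replicate 3 of that title. Those labelled FL pre-cDC2 replicates 1 and 2 held 777 and 696 CPM of Tlr3, against 286 in replicate 3 of theirs. A candidate explanation is that the titles of the 2 groups were exchanged, as their file names read. All 4 of the 4 libraries correlated better across genes with replicate 3 of the other title: 0.969 and 0.965 against 0.934 and 0.923 for those labelled FL cDC1, and 0.970 and 0.974 against 0.945 and 0.947 for those labelled FL pre-cDC2. With the 3 empty-vector WT cDC1 libraries, those labelled FL pre-cDC2 correlated at 0.966 to 0.979 and those labelled FL cDC1 at 0.912 to 0.935; genes are not independent replicates, and no biological explanation was tested.

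Genes with a single annotated transcript rarely reached high counts: the 99th percentile was 1.37 counts per base over 4262 such genes, against 16.2 in genes with 9 or more transcripts. Gene length is argued against, since among transcripts of 1 to 2 kb the percentile was still 12.2 times higher in genes with more transcripts (18.8 against 1.54). Removal of duplicate reads that match 1 transcript could limit such counts. Within groups, the count of 159 single-transcript genes with a mean of at least 0.8 counts per base grew with the library total at a median slope of 0.247 on log scales, against 1.04 in 2153 genes with more transcripts and the same mean. This explanation stays open, since the role of the listed tools is not known; if it held, it would compress fold changes of Lyz2, Id2, H2-Aa, H2-Ab1, H2-Eb1, B2m, Pgk1 and Tpi1, which lie between 0.85 and 1.61, while Ifi205, H2-D1 and H2-DMb1 lie well above the percentile, at 3.02, 3.10 and 4.34, and no biological explanation was tested.

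Hspa1a stood at 365 ± 38.9 CPM in WT cultured pre-cDC1 and at 3.23 ± 3.50, 2.71 ± 2.52 and 9.60 ± 11.7 in d32, d32het and d56het. A strain difference at this locus that acts at every stage is argued against, because the highest of 4 other WT cultured groups (MDP, CDP, cDC2 and empty-vector cDC1) reached only 3.04% of the pre-cDC1 level, although the libraries labelled FL cDC1 replicates 1 and 2 held 363 and 385 CPM. A heat-shock response of the WT libraries from handling may be the source. Over 18 other heat-shock genes median changes against WT (interval) were -0.096 (-0.27 to -0.02), -0.148 (-0.22 to 0.04) and -0.193 (-0.36 to 0.09). Hspa8 fell in all groups (-0.61, -0.81, -0.92) and Ahsa1 in d56het (-0.38, adjusted p = 0.0461). Dnaja4 rose in d32 (3.69 ± 2.44 CPM against 0 counts, adjusted p = 0.0336). Handling and genotype cannot be told apart, because every WT pre-cDC1 library shares both, and an effect of the deletions stays open and untested.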

How the results depend on the processing

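Genes near the count limit of single-transcript genes and replicate 3 of the primary groups were left out only after the result was seen; the other alternatives were planned. DESeq2 size factors, no filter on low counts and leaving out genes near the count limit kept all 18 counts of called genes within 1.5 times the main count. No named gene called in the main test changed its direction under an alternative other than keeping the conflicting libraries under their titles. Among named genes, 10 calls were lost with DESeq2 size factors, 27 with no filter, 1 without the genes near the count limit, 12 with all libraries in 1 fit, 172 with only the groups compared in the fit and 1006 over all fits that leave out 1 library, in which 3844 results stayed on their side. Without replicate 3 of the primary groups 33 were lost. Named genes gained a call in 4 cases with DESeq2, 2 with only the groups compared, 1 without primary replicate 3 and 1 with 1 library left out. With an estimated correlation 89 list calls were lost and 279 list results stayed on their side of the threshold. Of 50 genes changed 2-fold in simulated counts, 0 were recovered for spleen against marrow and 0 for primary pre-cDC1 against MDP, against 15 for cultured against primary pre-cDC1. How far depth, rather than the spread between libraries, limits this was not separated. The cause of each shift below was not tested.

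DESeq2 called more genes in 15 of 18 comparisons by over 1.5 times: 1130 in d32, 1293 in d32het and 2427 in d56het against WT, 259 in d32 against d32het, 697 in d56het against d32het, 914 and 1109 in d56 and d32 with IRF8 against WT, and 741 between those 2 groups. It called 545 in CDP against MDP, 1049 in cDC1 against pre-cDC1, 273 in pre-cDC1 against pre-cDC2, 2266 in primary pre-cDC1 against MDP, 1089 in spleen against marrow, 1892 in cultured against primary MDP and 2430 in the interaction. With only the groups compared in the fit, and so with fewer libraries, edgeR called 1098 in d32, 184 in d32het, 1 in d32 against d32het, 0 in d56het against d32het (839 at an unadjusted p under 0.05), 81 in d32 with IRF8, 68 between the rescued groups, 26 in CDP against MDP, 3 in cDC1 against pre-cDC1, 0 in pre-cDC1 against pre-cDC2 (1041 at an unadjusted p under 0.05), 3188 in primary pre-cDC1 against MDP and 89 in spleen against marrow. Without replicate 3 of the primary groups it called 593 in spleen against marrow and 2409 in the interaction.

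When any 1 library was left out, the counts ran from 223 to 335 in d32, 135 to 369 in d32het, 793 to 1261 in d56het, 1 to 8 in d32 against d32het, 39 to 67 in d56het against d32het, 55 to 95 in d56 with IRF8, 82 to 143 in d32 with IRF8 and 33 to 97 between the rescued groups. They ran from 61 to 105 in CDP against MDP, 2388 to 2604 in pre-cDC1 against CDP, 1714 to 2073 in cDC1 against cDC2, 135 to 206 in cDC1 against pre-cDC1, 13 to 23 in pre-cDC1 against pre-cDC2, 455 to 794 in primary pre-cDC1 against MDP, 68 to 1152 in spleen against marrow, 585 to 852 and 1882 to 2686 in cultured against primary MDP and pre-cDC1, and 861 to 1893 in the interaction.

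With the conflicting libraries kept under their titles, 23 genes were called in cDC1 against pre-cDC1 and 1 in pre-cDC1 against pre-cDC2. The sign then turned for Snx22 (-0.04, adjusted p = 0.98), Cd7 (0.25, adjusted p = 0.931), Siglech (1.01, adjusted p = 0.593) and Ly6c2 (4.40, adjusted p = 0.193) in the first and Trim32 (-0.28, adjusted p = 0.944) in the second, and 34 other named calls were lost. Among named genes not called, Cadm1 (3.70 for spleen against marrow) turned to -3.39 with the replicate block (adjusted p = 0.8) and to -7.92 without splenic replicate 3 (adjusted p = 0.00299; range over left-out libraries -7.92 to 4.29), and likewise to -7.92 without replicate 3 of the primary groups (adjusted p = 0.032). Both values of -7.92 are fitted against 2 spleen libraries at 0.0593 and 0 CPM, and give no bound. Irf8 between cDC1 and pre-cDC1 turned from -0.01 to 0.06 with DESeq2 and with its size factors, 0.02 with the replicate block 0.01 with only these libraries and 0 to 2 decimals with no filter on low counts, and lay between -0.03 and 0.02 when a library was left out. Values close to 0 also turned sign when a library was left out for Irf8 in d56 with IRF8 (-0.03 to 0.06), CDP against MDP (-0.01 to 0.22) and cultured against primary MDP (-0.06 to 0.06, and 0 to 2 decimals with no filter), and for Xcr1 in d56 with IRF8 (-0.03 to 0.06).

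In none of the 16 comparisons with 3 numbered pairs did every same-number pair of libraries deviate together with a correlation over 0.1. The lowest correlation lay between -0.093 and 0.026. That rule asks for every pair, so it cannot exclude a batch that only some pairs share. In the sample list, replicate 3 libraries stand in a block apart from replicates 1 and 2. Whether that block is a batch was not tested. Every library correlated best with its own number in 2 comparisons, d32 against d32het and spleen against marrow. With the replicate block, 1 gene was called in d32 against d32het, 17 in d56het against d32het, 118 and 105 in d56 and d32 with IRF8, 50 between the rescued groups, 125 in cDC1 against pre-cDC1, 4 in pre-cDC1 against pre-cDC2, 560 in primary pre-cDC1 against MDP and 65 in spleen against marrow, and the other 9 counts stayed within 1.5 times. Of named genes 165 lost the call with the block.

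Splits of 3 libraries against 3 number 10, too few for a share under 0.05. In each of these 15 comparisons 1 split gave as many genes, the real one. Real count and highest other were 524 and 0 for d32, 431 and 0 for d32het, 1438 and 1 for d56het, 8 and 1 for d32 against d32het, 61 and 20 for d56het against d32het, 192 and 0 for d56 with IRF8, 241 and 2 for d32 with IRF8 and 122 and 1 between the rescued groups. They were 138 and 1 for CDP against MDP, 3101 and 0 for pre-cDC1 against CDP, 2411 and 2 for cDC1 against cDC2, 1085 and 0 for primary pre-cDC1 against MDP, 247 and 0 for spleen against marrow, 997 and 1 for cultured against primary MDP and 2634 and 1 for cultured against primary pre-cDC1.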

Other observations

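Cultured pre-cDC1 also differed from primary bone marrow pre-cDC1 in class II, transcription factor, interferon and cell cycle genes. Of 12 class II genes 9 were higher in culture and 1, Ifi30, was lower (10 and 1 adjusted over the list alone). They included Cd74 (21750 ± 2090 against 824 ± 513 CPM) and H2-Ob (75.6 ± 6.82 against 7.35 ± 1.52 CPM), with a camera adjusted p of 2.65e-09 (0.0303 with an estimated correlation). Transcription factors of DCs went both ways, 9 higher and 9 lower of 28 (9 and 9 adjusted over the list alone), with a median of 0.19, a mean of 0.01 and a set test pointing downwards (adjusted p = 0.85). Nfil3 (2.45, SE 0.23), Bcl6 (1.58, SE 0.15) and Runx3 were higher in culture, and Zeb2 (41.8 ± 25.9 against 569 ± 48.5 CPM), Bcl11a (-2.19, SE 0.19) and Tcf4 were lower. Interferon-stimulated genes were lower in 4 of 17 (4 adjusted over the list alone; camera adjusted p = 0.0121, and p = 0.0481 with an estimated correlation), among them Irf7 (71.1 ± 18.6 against 186 ± 25.7 CPM) and Usp18. Cell cycle genes were lower in 11 of 21 and higher in 1, Mcm7 (2 higher and 11 lower adjusted over the list alone), led by Plk1 (-0.92, SE 0.12) and Mki67 (-0.72, SE 0.11); the camera adjusted p was 0.00162 and p = 0.246 with an estimated correlation.

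In pre-cDC1 with a deleted enhancer, Ifih1, the RNA sensor MDA5, was 8.81 ± 1.55 CPM in WT and 28.9 ± 3.34, 25.8 ± 12.8 and 26.3 ± 9.35 in d32, d32het and d56het. It was higher by 1.71, 1.55 and 1.59 on the log2 scale (adjusted p = 0.0274, 0.0464 and 0.0186). Interferon-stimulated genes gave 1, 1 and 2 higher of 16 (2, 1 and 5 higher and 0, 0 and 1 lower adjusted over the list alone). The camera adjusted p was 0.000362, 0.504 and 0.0512, and with an estimated correlation p = 0.0155, 0.646 and 0.156. In d32het the list median was 0.83 and its mean -0.04.

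Cd79b was the single B cell gene of 13 measured in the genotype fit. It stood at 8.47 ± 3.65 CPM in WT, 32.0 ± 3.88 in d32 (1.91, SE 0.36, adjusted p = 0.0146) and 40.9 ± 13.2 in d56het (2.28, SE 0.36, adjusted p = 0.00284), so 1 of 1 rose in each. In d32het it stood at 19.6 ± 6.40 CPM (1.20, SE 0.35, adjusted p = 0.0956), where edgeR called 0 of 1 (1 higher at an unadjusted p under 0.05, 1 by DESeq2 and 1 adjusted over the list alone). It was also lower in cultured pre-cDC1 than in CDP (-2.33, SE 0.49) and in primary bone marrow pre-cDC1 (-2.43, SE 0.31), 1 of 4 each time (3 adjusted over the list alone). For primary pre-cDC1 against MDP, edgeR called 0 of 13 B cell genes (1 higher and 1 lower at an unadjusted p under 0.05, 0 by DESeq2), and for spleen against marrow 0 of 13 (3 higher and 1 lower, and 2 higher by DESeq2). Of 5 T, NK and innate lymphoid cell genes, Il7r rose in d56het (38.1 ± 1.25 against 2.83 ± 3 CPM, adjusted p = 0.0397) and Klrb1c fell (1 and 1 adjusted over the list alone). That list's median was 2.92 and its mean -0.05.

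The genes higher in primary pre-cDC1 than in primary MDP, a list made from other libraries of the same study, moved both ways with the deletions. Of 100 measured, 12 rose and 10 fell in d32 (25 and 15 adjusted over the list alone), 11 and 4 in d32het (18 and 16) and 18 and 20 in d56het (28 and 27), with camera adjusted p = 0.583, 0.191 and 0.876. In d32 with IRF8, 8 rose and 2 fell (24 and 7 adjusted over the list alone; camera adjusted p = 0.00164, and p = 0.177 with an estimated correlation). Of 73 genes higher in primary MDP, 3, 2 and 4 rose and 0, 0 and 7 fell in d32, d32het and d56het (3, 2 and 4 higher and 0, 0 and 9 lower adjusted over the list alone; camera adjusted p = 0.0713, 0.491 and 0.519).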
